A study of Drosophila melanogaster with 30 samples.

How the data were processed

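Nuclear RNA of Drosophila melanogaster was measured, per the labels in nuclei of the mushroom body, the brain structure in which fly olfactory memories form. Per the labels' protocols, fly heads were crosslinked, nuclei carrying a FLAG tag were pulled out of the homogenate with an anti-FLAG gel, polyadenylated RNA was selected with oligo-dT beads and libraries were made with the NEBNext Ultra II RNA kit. The same protocols state that neurons were activated by red light through CsChrimson, a light-gated cation channel. The activated libraries come from flies given 5 min of activation and 10 min of rest, and the naive libraries from flies that were not activated. The labels name the lines MB131 and MB477, each with and without RNA interference (RNAi) against Kdm4B, and flies lacking CsChrimson whose line is not named. Samples were placed in 10 groups of 3 libraries by their titles. The labels do not say that replicates came from separate flies or cultures, so the p-values measure only the spread between these libraries, which may be technical.

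The deposited count table holds whole-number read counts for 17559 genes in 30 libraries. Per the submitters' processing notes, reads were aligned with STAR to the dm6 genome and counted with HTSeq, with no versions given. Whether counting used strand and how reads matching several places were treated are not given in the sources used here, so near-identical gene copies (the Hsp70 genes) and overlapping genes on opposite strands are uncertain. A table of the authors' own comparisons was also deposited; it gives a log2 fold change and an adjusted p-value for each gene and comparison, and DESeq2 is the tool the submitters' processing notes name for it. Its log2 column for activated MB477 flies with and without RNAi runs in the opposite direction to the others: all 2163 genes past its threshold that were compared had the opposite sign to the counts (Pearson r across genes -0.999), against r of at least 0.999 for the other columns. Values from that column are given with their sign turned. Genes were matched by FlyBase identifier because 5 names had been altered to dates and 4491 differ from current ones; 17253 identifiers were found in the reference names and 306 were not. Positions are dm6 coordinates from the Ensembl annotation of the same assembly (BDGP6).

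Total counts ran from 8291599 to 14344348 per library, with a median of 11458759. Counts were analysed as deposited in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr with a minimum count of 10 and a minimum total of 15, which left 11457 genes holding at least 99.9% of the counts of every library; 1384 genes had no count anywhere. Libraries were scaled with TMM factors. All 30 libraries entered a single model with a mean per group and no other terms, so that every comparison shares the same estimate of the spread, whose typical biological coefficient of variation was 6.32%. Each comparison was tested with edgeR's quasi-likelihood F test (robust glmQLFit) for change in either direction, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 15 comparisons are 5 of activated with naive libraries, 4 of RNAi with no RNAi, 5 interactions (differences between such differences) and the naive groups of the lines. Log2 fold changes are printed with standard errors (SE) derived from the test, as the absolute change divided by the square root of the F statistic. The p-values also use degrees of freedom that can differ between genes, so the SE need not rank as they do. Levels are CPM (counts scaled to a fixed library total) as mean ± SD over 3 libraries, and floors cover counting error only, since PCR copies are not independent molecules. The interval printed for Kdm4B is the fitted change ± 1.96 SE and includes the model's spread between libraries. A prior count of 2 was used for log2 CPM.

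For gene groups, 37 lists of pathways, complexes and cell type markers that fly heads could hold were tested with camera (limma 3.58.1) on log2 CPM of the same model, with the preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 36 lists that had at least 3 tested genes. The same test with a correlation estimated per list and the fry test were run beside it. Counts of members are given over all genes tested and adjusted over the list alone.

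The model, the comparisons, the lists, the rule for named genes and all alternatives but 2 were fixed before the data were examined. By that rule, the genes named per comparison are those past the test whose groups do not overlap in CPM (which chance alone gives to 10% of genes for 3 libraries against 3), the 10 with the largest increase and the 10 with the largest decrease (5 and 5 for interactions, without the overlap condition), up to 4 members past the test with the largest change from each list, and Kdm4B, Hr38, sr and kay throughout; the text names some of them. Alternatives were relative log expression size factors, no filter on low counts, the replicate number as a block, a model of only the compared groups, DESeq2 1.42.0, limma-voom with sample weights and leaving out each library in turn. A test against a 1.5-fold change and a model without the MB477 naive libraries were added after seeing the data.

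The procedure was tested on simulated counts drawn for the 11457 genes from the real means and library sizes. In a simulated comparison of activated with naive MB131 libraries, 31.3% of genes changed by 1.25-fold were recovered, 53.7% at 1.5-fold and 72.7% at 2-fold, and 9 unchanged genes were called. For the simulated MB131 interaction the shares were 14.9%, 37.3% and 77.3%, with 4 unchanged genes called. In both, camera called a list of 20 genes raised by 1.5-fold and 0 of 35 unchanged lists. The simulated genes were drawn independently of each other, so this could not show how often camera calls unchanged lists whose genes vary together. Replicates of every group differed by more than sampling noise (chi-square per degree of freedom 2.84 to 6.90), so no library appeared to be a copy of another in its group. Libraries of different groups were not compared in this way.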

Results

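Nuclear RNA was counted in 30 libraries of what the labels give as mushroom body nuclei, 3 for each of 10 groups: naive and activated flies of the lines MB131 and MB477, of the same lines with RNAi against Kdm4B, and of flies without CsChrimson. The series title gives finding genes controlled by Kdm4B, a histone lysine demethylase, as the aim. Libraries held 8291599 to 14344348 counts. On the first principal component of log2 CPM, which held 26.8% of the variance, the 3 MB477 naive libraries lay at 64.2 to 68.0 and the other 27 at -25.5 to 22.9. Of these 27, those of MB477 lay highest, with the activated ones at 18.5 to 22.9 and the RNAi naive ones at most at 4.56. The MB131 libraries and those without CsChrimson lay at -25.5 to -12.8. The second component held 17.6%. Markers of other head tissues were abundant beside those of Kenyon cells, the intrinsic neurons of the mushroom body, although lists of different genes do not give shares of cells. Mean log2 CPM over the members of each list in naive MB131 flies was 8.19 for Kenyon cell, 8.06 for photoreceptor, 7.89 for muscle, 7.18 for glia and 6.83 for fat body markers, and in naive MB477 flies 6.96, 7.84, 8.28, 6.95 and 7.55. In naive MB131 flies ninaE, the rhodopsin gene of photoreceptors, stood at 8364 ± 272 CPM and the Kenyon cell marker sNPF at 528 ± 18.5 CPM (SD, n = 3). The libraries thus hold RNA from outside the mushroom body, of a share that was not measured, and every comparison covers it. Whether that share differs between the compared groups was not measured either. A shift of a whole marker list need therefore not be a change of expression within cells.

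**Figure D1:**
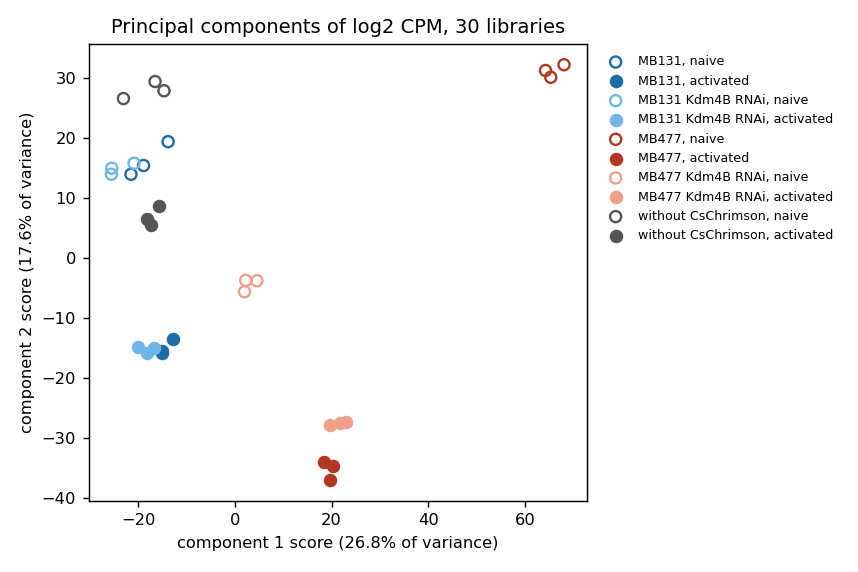
Principal components of log2 CPM over the 11457 tested genes, a point per library, coloured by line and genotype, with open symbols for naive and filled symbols for activated flies. The axes give component scores and their percent of the variance; the 3 MB477 naive libraries lie apart at 64.2 to 68.0 on the first component.

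Kdm4B (FBgn0053182, 2R from 13176553 to 13198337), the gene targeted by RNAi, was covered by 2 to 26 reads per library, and group means ran from 0.559 to 1.15 CPM. In naive MB131 flies its level was 0.911 ± 0.142 CPM without and 1.08 ± 0.448 CPM with RNAi (SD, n = 3), a log2 fold change of 0.24 ± 0.61 (edgeR adjusted p = 0.889). In activated MB131 flies the change was -0.36 ± 0.60 (edgeR adjusted p = 0.802), in naive MB477 flies -0.09 ± 0.63 (0.912) and in activated MB477 flies -1.05 ± 0.67 (0.285), where the 95% interval ran from 0.194-fold to 1.19-fold. A lower Kdm4B transcript level in the RNAi groups was not detectable at this depth, and the labels of the knockdown groups could not be checked by it.

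Heat shock genes, which encode protein chaperones, rose with activation in every genotype, flies without CsChrimson included. Of the 21 heat shock and chaperone genes tested, 19 rose in MB131, 19 in MB131 with RNAi, 20 in MB477, 19 in MB477 with RNAi and 19 without CsChrimson (19, 19, 20, 21 and 19 adjusted over the list alone). Their median log2 fold changes were 2.21, 2.57, 3.02, 2.74 and 2.28, and camera called the list in all 5 comparisons (adjusted p = 5.39e-15 at most), also with an estimated correlation (adjusted p = 1.62e-04 at most). Hsp26, a small heat shock protein gene (3L from 9376418 to 9377427), went from 19.1 ± 1.42 to 789.9 ± 10.5 CPM in MB131 and from 11.2 ± 0.646 to 339 ± 14.9 CPM without CsChrimson (SD, n = 3). The 5 comparisons share no libraries; 276 genes rose and 168 fell in all of them, against 1.11 and 0.631 for independent lists. Beside chaperone genes such as DnaJ-1 and stv, those that rose include Hsromega, a noncoding heat shock RNA, tra, a regulator of sexual differentiation, and the photoreceptor genes ninaE and chp.

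**Figure D2:**
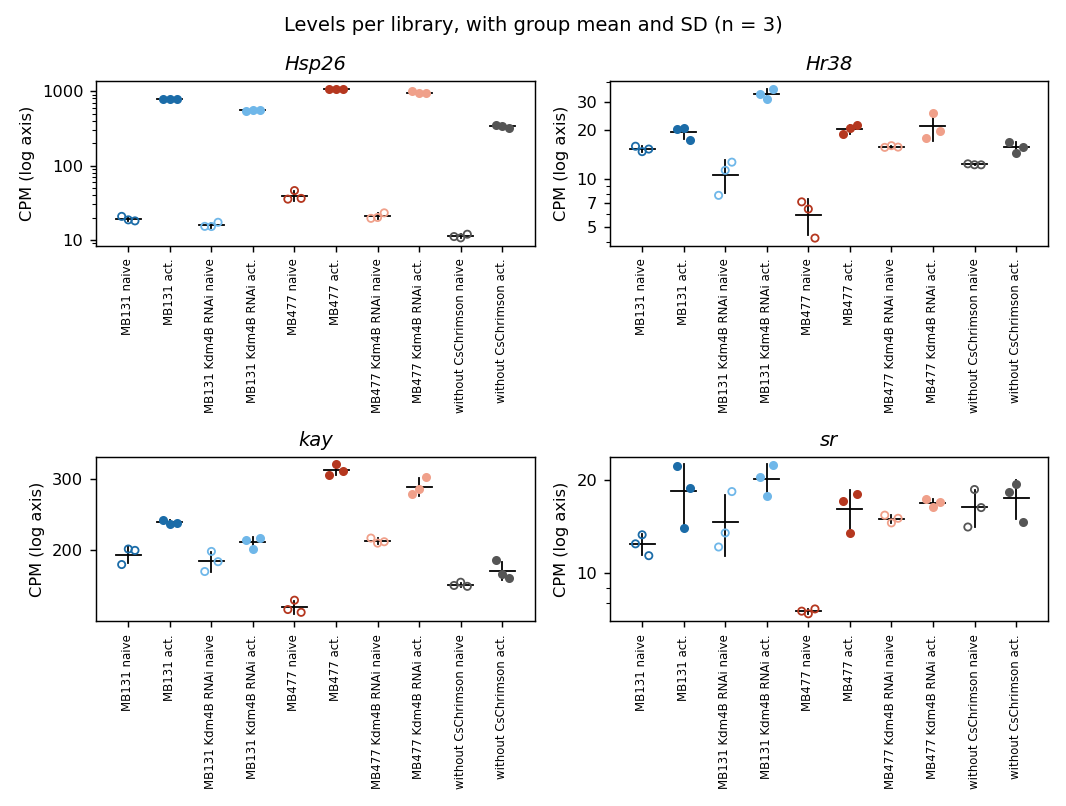
Levels of Hsp26, Hr38, kay and sr in CPM on log axes, a point per library and a horizontal bar at the mean of each of the 10 groups (n = 3), with vertical bars for the SD. Hsp26 lies at 19.1 CPM in naive and 789.9 CPM in activated MB131 flies.

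In MB131, 1459 of 11457 genes were higher and 1347 lower in activated than in naive flies, 238 of them by more than 2-fold. Hsp26 changed by 5.37 ± 0.06 and Hsp68, an Hsp70-type chaperone, by 5.29 ± 0.11 on the log2 scale (SE; edgeR adjusted p = 7.82e-88 and 3.07e-20). Among activity-regulated genes, transcripts that neurons induce when they fire, 9 of 17 rose (10 adjusted over the list alone, camera adjusted p = 0.00169), with kay, the fly Fos gene, at 0.27 ± 0.05 and sr, the fly Egr gene, at 0.57 ± 0.15. Hr38, a nuclear receptor gene of this list, had 0.34 ± 0.14 (edgeR adjusted p = 0.0687) and did not pass. It passed without MB131 activated replicate 3 (0.43, adjusted p = 0.0408; 0.0408 to 0.190 over the alternatives fixed beforehand). The rise of sr did not pass without replicate 1 (0.42, adjusted p = 0.0672; 2.73e-04 to 0.0672 over these). Photoreceptor markers rose in 20 of 26 (22 adjusted over the list alone, camera adjusted p = 2.76e-18), among them ninaE, which encodes rhodopsin 1 (0.74 ± 0.03), and chp (0.93 ± 0.05). Peptidergic markers rose in 15 of 27 (18 adjusted over the list alone, camera adjusted p = 5.98e-06), with the neuropeptide gene AstC at 0.73 ± 0.12.

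In the same comparison 17 of 32 antimicrobial and stress peptide genes fell (17 adjusted over the list alone, camera adjusted p = 1.39e-06, and 0.0178 with an estimated correlation), among them Dpt, an antibacterial diptericin (-1.63 ± 0.26). Cuticle and epidermis genes fell in 20 of 62 (21 adjusted over the list alone, camera adjusted p = 2.20e-05), with Cpr97Ea at -2.44 ± 0.20, while Cpr66D rose (2.32 ± 0.23). Fat body markers rose in 12 of 18 (12 adjusted over the list alone) and muscle markers fell in 13 of 20 (14); both passed camera, but with adjusted p = 0.0582 and 0.126 with an estimated correlation. The yolk protein genes Yp1 (0.97 ± 0.05), Yp2 (0.99 ± 0.06) and Yp3 (0.99 ± 0.05) rose, and so did 6 of 12 sex-biased genes (6 adjusted over the list alone, camera adjusted p = 0.00210). The clock genes tim (-0.60 ± 0.04) and vri (-0.70 ± 0.06) fell, in a list of CREB and circadian regulators of which 6 of 13 fell (7 adjusted over the list alone), with adjusted p = 0.147 with an estimated correlation. Kenyon cell markers fell in 12 of 23 (15 adjusted over the list alone, median -0.16), with adjusted p = 0.404 with an estimated correlation.

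With Kdm4B RNAi in MB131, 1581 genes were higher and 1484 lower in activated than in naive flies. Hr38 rose from 10.6 ± 2.48 to 33.8 ± 2.66 CPM (1.68 ± 0.14 on the log2 scale; edgeR adjusted p = 1.96e-18), and 10 of 17 activity-regulated genes rose (10 adjusted over the list alone, camera adjusted p = 0.00116). Muscle markers fell in 18 of 20 (19 adjusted over the list alone, median -0.78, camera adjusted p = 4.54e-22), with the flight muscle actin Act88F at -1.68 ± 0.21, the myosin light chain Mlc1 at -1.18 ± 0.06 and paramyosin (Prm) at -1.03 ± 0.05. Fat body markers rose in 13 of 18 (13 adjusted over the list alone), photoreceptor markers in 23 of 26 (24), peptidergic markers in 20 of 27 (20) and oxidative stress and detoxification genes in 14 of 27 (16); each passed camera, also with an estimated correlation. Examples are Yp3 (1.43 ± 0.05), ninaE (0.96 ± 0.03), AstC (1.06 ± 0.12) and the glutathione transferase GstE3 (0.89 ± 0.09). Cuticle and epidermis genes fell in 23 of 62 (23 adjusted over the list alone, camera adjusted p = 5.14e-06). Cytoplasmic ribosomal protein genes rose in 74 of 84 (75 adjusted over the list alone, median 0.23), with adjusted p = 0.243 with an estimated correlation. The changes of kay (0.16 ± 0.05) and sr (0.46 ± 0.15) depended on single libraries. Without MB131 RNAi naive replicate 1 or activated replicate 3, kay had 0.12 and 0.14 (adjusted p = 0.127 and 0.0623; 0.00347 to 0.127 over the alternatives fixed beforehand). Without these or naive replicate 2, sr had 0.34, 0.38 and 0.41 (adjusted p = 0.133, 0.0951 and 0.0676; 0.00140 to 0.133 over the alternatives fixed beforehand).

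The question whether RNAi altered the response to activation was tested as the interaction. In MB131, 374 genes responded more positively and 320 more negatively with RNAi. Hr38 was among the first (1.33 ± 0.20; edgeR adjusted p = 3.82e-07), with kay at -0.11 ± 0.07 (adjusted p = 0.478) and sr at -0.11 ± 0.21 (adjusted p = 0.886) not passing. Antimicrobial and stress peptide genes responded more positively in 19 of 32 (24 adjusted over the list alone, median 0.93, camera adjusted p = 7.03e-19), with Dpt at 2.75 ± 0.34. Muscle markers responded more negatively in 16 of 20 (16 adjusted over the list alone, median -0.55, camera adjusted p = 7.90e-25), for example Prm (-0.71 ± 0.07) and Mlc1 (-0.69 ± 0.08). Photoreceptor markers (6 of 26 more positive, 9 adjusted over the list alone) and sex-biased genes (4 of 12, 5 adjusted over the list alone) also passed, and all 4 lists held with an estimated correlation (adjusted p = 0.0382 at most). Kenyon cell markers responded more positively in 10 of 23 (16 adjusted over the list alone, median 0.23), with adjusted p = 0.0895 with an estimated correlation.

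In MB477, 3643 genes were higher and 3170 lower in activated than in naive flies, 1711 by more than 2-fold; the naive libraries of this comparison are those that lay apart on the first principal component. Hr38 rose from 5.96 ± 1.52 to 20.4 ± 1.3 CPM (1.76 ± 0.16), kay by 1.13 ± 0.05 and sr by 1.10 ± 0.17 on the log2 scale (edgeR adjusted p = 3.58e-17, 1.08e-37 and 1.21e-08). Activity-regulated genes rose in 12 of 17 (12 adjusted over the list alone, camera adjusted p = 0.00205, and 0.0215 with an estimated correlation). Photoreceptor markers rose in 18 of 26 (19 adjusted over the list alone, camera adjusted p = 5.21e-04), with ninaE at 1.49 ± 0.03. Cuticle and epidermis genes fell in 45 of 62 (45 adjusted over the list alone, median -1.18, camera adjusted p = 2.17e-08), with Cpr97Ea at -3.08 ± 0.22. Presynaptic release genes rose in 22 of 24 (22 adjusted over the list alone, median 0.96), among them cpx, encoding complexin (1.71 ± 0.04), and brp, a scaffold of the active zone (1.56 ± 0.09), with adjusted p = 0.104 with an estimated correlation. Kenyon cell markers rose in 17 of 23 (17 adjusted over the list alone), with the neuropeptide gene sNPF at 1.89 ± 0.05 and the adenylate cyclase gene rut at 1.32 ± 0.08, but adjusted p = 0.294 with an estimated correlation. Cytoplasmic ribosomal protein genes fell in 68 of 84 (69 adjusted over the list alone, adjusted p = 0.330 with an estimated correlation) and nuclear-encoded oxidative phosphorylation genes in 65 of 75 (65; adjusted p = 0.104 with an estimated correlation), with RpL39 at -0.75 ± 0.08.

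With Kdm4B RNAi in MB477, 1792 genes were higher and 1501 lower in activated than in naive flies. Oxidative stress and detoxification genes rose in 21 of 27 (21 adjusted over the list alone, median 0.36, camera adjusted p = 1.65e-10, and 0.00165 with an estimated correlation), for example GstE3 (1.61 ± 0.08) and GstD10 (1.31 ± 0.23). Activity-regulated genes rose in 9 of 17 (9 adjusted over the list alone, camera adjusted p = 1.28e-05, and 0.00165 with an estimated correlation), kay by 0.45 ± 0.05. Hr38 passed at 0.42 ± 0.14 (edgeR adjusted p = 0.0179) but not without MB477 RNAi naive replicate 1 (0.42, adjusted p = 0.0506) or activated replicate 2 (0.25, adjusted p = 0.265; 0.00811 to 0.265 over the alternatives fixed beforehand), and sr had 0.17 ± 0.15 (adjusted p = 0.462). Among the largest rises were Hsp68 (5.94 ± 0.12), Hsp26 (5.53 ± 0.06) and Hsp27 (5.09 ± 0.09). Kenyon cell markers fell in 17 of 23 (17 adjusted over the list alone, median -0.33) and presynaptic release genes in 17 of 24 (18), with prt at -0.59 ± 0.07 and brp at -0.44 ± 0.08; adjusted p = 0.0650 and 0.199 with an estimated correlation. Ribosomal protein genes rose in 81 of 84 (81 adjusted over the list alone, adjusted p = 0.0983 with an estimated correlation). Muscle markers rose in 15 of 20 (15 adjusted over the list alone), fat body markers in 12 of 18 (13) and photoreceptor markers in 11 of 26 (12), with adjusted p = 0.0807, 0.0650 and 0.0611 with an estimated correlation.

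In MB477 the interaction with RNAi called 2829 genes with a more positive and 3083 with a more negative response under RNAi. It uses the MB477 naive libraries that lie apart, so differences in the naive levels enter every gene and list below. Hr38 (-1.34 ± 0.22), kay (-0.68 ± 0.07) and sr (-0.93 ± 0.23) responded more negatively with RNAi (edgeR adjusted p = 1.21e-07, 1.17e-14 and 3.09e-04). Their naive levels differed too. Hr38 stood at 5.96 ± 1.52 CPM in MB477 and 15.8 ± 0.211 CPM in MB477 with RNAi before activation. Cuticle and epidermis genes responded more positively in 35 of 62 (36 adjusted over the list alone, median 1.20, camera adjusted p = 9.65e-07, and 0.00683 with an estimated correlation). Presynaptic release genes responded more negatively in 22 of 24 (22 adjusted over the list alone), Kenyon cell markers in 19 of 23 (19) and dopamine and other amine receptors in 12 of 16 (12), with sNPF at -2.28 ± 0.07 and brp at -2.0 ± 0.12; adjusted p = 0.0878, 0.124 and 0.0970 with an estimated correlation. The fold changes of activation in MB477 with and without RNAi, which also use those naive libraries, had a Pearson correlation across genes of 0.0356 (genes are not independent replicates). In these, 1258 genes were called in opposite directions, 726 were higher in both (569.8 for independent lists) and 455 lower in both (415). No value for independent lists was computed for opposite calls. Activation in MB477 without RNAi called 59.5% of tested genes, so many of the 1258 could arise from independent lists. For MB131 the correlation was 0.507, with 44 opposite calls, 913 genes higher in both (201 for independent lists) and 770 lower in both (174).

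Without CsChrimson, 1267 genes were higher and 1143 lower in flies given the protocol than in naive flies. Photoreceptor markers rose in 23 of 26 (23 adjusted over the list alone, median 0.54, camera adjusted p = 3.94e-26), among them inaD (1.21 ± 0.04) and trp (0.91 ± 0.04) of phototransduction. Peptidergic markers rose in 15 of 27 (15 adjusted over the list alone, camera adjusted p = 2.95e-05) and oxidative stress and detoxification genes in 13 of 27 (14; camera adjusted p = 4.84e-06); these lists held with an estimated correlation. Hr38 had 0.36 ± 0.15, kay 0.12 ± 0.05 and sr 0.10 ± 0.15 (edgeR adjusted p = 0.0764, 0.0985 and 0.722), none past the threshold. Activity-regulated genes rose in 6 of 17 (8 adjusted over the list alone), with adjusted p = 0.0778 with an estimated correlation. The clock genes tim (-1.35 ± 0.04), vri (-1.76 ± 0.06), per (-0.85 ± 0.07) and Pdp1 (-0.81 ± 0.04) fell, and 7 of 13 CREB and circadian regulators fell (7 adjusted over the list alone, adjusted p = 0.10 with an estimated correlation). Muscle markers fell in 14 of 20 (16 adjusted over the list alone, adjusted p = 0.10 with an estimated correlation).

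The response of each line was compared with that of the flies without CsChrimson. The same 6 libraries without CsChrimson serve both lines and their line is not named, so for at least 1 line the comparison mixes line with CsChrimson. In MB131 309 genes responded more positively and 405 more negatively than without CsChrimson. Hr38 (-0.02 ± 0.21), kay (0.15 ± 0.07) and sr (0.47 ± 0.22) did not differ past the threshold (edgeR adjusted p = 0.987, 0.248 and 0.227). Fat body markers responded more positively in 10 of 18 (11 adjusted over the list alone, median 0.38), with Yp1 at 1.18 ± 0.06, Yp2 at 1.17 ± 0.09 and Yp3 at 1.19 ± 0.07. Kenyon cell markers responded more negatively in 15 of 23 (16 adjusted over the list alone, median -0.31), with sNPF at -0.44 ± 0.06, prt at -0.56 ± 0.09 and the dopamine receptor gene Dop1R2 at -0.48 ± 0.09. Photoreceptor markers did so in 11 of 26 (12 adjusted over the list alone) and cuticle genes in 13 of 62 (15). Camera adjusted p = 1.03e-07, 1.13e-12, 1.16e-05 and 1.18e-05, and 0.0415, 0.0415, 0.00402 and 0.00822 with an estimated correlation. The naive flies without CsChrimson differed in clock gene level from every other group: tim stood at 2121 ± 169 CPM, and next highest at 1081 ± 44.9 CPM in naive MB131 flies. These naive flies without CsChrimson enter the comparison of either line.

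In MB477 3042 genes responded more positively and 2314 more negatively than without CsChrimson. Hr38 (1.40 ± 0.22), kay (1.02 ± 0.07) and sr (1.0 ± 0.23) responded more positively (edgeR adjusted p = 7.60e-08, 2.75e-23 and 1.08e-04). Activity-regulated genes did so in 12 of 17 (12 adjusted over the list alone), with adjusted p = 0.0773 with an estimated correlation. Cuticle genes responded more negatively in 31 of 62 (31 adjusted over the list alone, median -0.94, camera adjusted p = 1.02e-07, and 0.00285 with an estimated correlation). Between the lines, 2873 genes responded more positively and 2158 more negatively in MB477 than in MB131, with Hr38 at 1.41 ± 0.22, kay at 0.87 ± 0.07 and sr at 0.53 ± 0.23 (edgeR adjusted p = 3.37e-08, 1.65e-19 and 0.04996). For sr the adjusted p was 0.0126 to 0.183 over the alternatives fixed beforehand, and it did not pass under any that kept all libraries. Presynaptic release genes responded more positively in 22 of 24 (22 adjusted over the list alone), with adjusted p = 0.129 with an estimated correlation. Both comparisons rest on the MB477 naive libraries, which stand apart.

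What Kdm4B RNAi altered without activation was tested in naive flies. In MB131 564 genes were higher and 701 lower with RNAi, and 824 in all were called without MB131 naive replicate 1. The leucine-rich repeat gene CG18095 (2L from 14029262 to 14031539) was higher with RNAi, at 0.140 ± 0.128 CPM without and 15 ± 2.71 CPM with it, and so was the neighbouring noncoding gene CR45284 (4.79 ± 0.45). Muscle markers were lower in 16 of 20 (17 adjusted over the list alone, median -0.26), with the actin gene Act79B at -1.67 ± 0.08. Photoreceptor markers were lower in 13 of 26 (15 adjusted over the list alone), with ninaE at -0.48 ± 0.03, and heat shock genes were lower in 10 of 21 (10 adjusted over the list alone), with Hsp83, the fly Hsp90 gene, at -0.64 ± 0.03. Glia markers were higher in 7 of 23 (8 adjusted over the list alone). Camera called these 4 lists with adjusted p = 6.19e-14, 3.13e-10, 3.57e-07 and 0.00130, also with an estimated correlation. Ribosomal protein genes were lower in 66 of 84 (75 adjusted over the list alone) and oxidative phosphorylation genes in 50 of 75 (58), with adjusted p = 0.165 and 0.0590 with an estimated correlation. Hr38 was lower (-0.53 ± 0.15; edgeR adjusted p = 0.00926) but did not pass without MB131 RNAi naive replicate 1 (-0.36, adjusted p = 0.175; 0.00345 to 0.175 over the alternatives fixed beforehand).

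In activated MB131 flies 669 genes were higher and 647 lower with RNAi. Antimicrobial and stress peptide genes were higher in 20 of 32 (23 adjusted over the list alone, median 0.71, camera adjusted p = 1.84e-18), Dpt by 2.32 ± 0.25. Muscle markers were lower in 18 of 20 (19 adjusted over the list alone, median -0.84, camera adjusted p = 1.76e-43), with Act79B at -1.37 ± 0.08, the troponin C gene TpnC41C at -0.95 ± 0.11 and Mp20 at -0.96 ± 0.07. Oxidative phosphorylation genes were lower in 58 of 75 (59 adjusted over the list alone), photoreceptor markers in 11 of 26 (12) and heat shock genes in 8 of 21 (10), with the small heat shock protein gene l(2)efl at -1.09 ± 0.07; all 5 lists held with an estimated correlation (adjusted p = 0.0240 at most). Hr38 was higher with RNAi (0.80 ± 0.14; edgeR adjusted p = 2.19e-06). The kekkon family gene kek2 (2L from 11581937 to 11626883) was lower, at 215 ± 8.50 CPM without and 34.5 ± 0.735 CPM with RNAi (-2.64 ± 0.07).

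In naive MB477 flies 3511 genes were higher and 3492 lower with RNAi, against the naive libraries that lie apart. Cuticle and epidermis genes were lower in 36 of 62 (38 adjusted over the list alone, median -0.89, camera adjusted p = 4.03e-05, and 0.0325 with an estimated correlation), for example Cpr35B (-4.39 ± 0.80) and TwdlZ (-2.33 ± 0.49). Kenyon cell markers were higher in 20 of 23 (20 adjusted over the list alone, median 1.15), with sNPF at 2.81 ± 0.05, the vesicular transporter gene prt at 2.37 ± 0.08 and rut at 2.12 ± 0.08; adjusted p = 0.0870 with an estimated correlation. Presynaptic release genes were higher in 22 of 24 (22 adjusted over the list alone, adjusted p = 0.104 with an estimated correlation) and ribosomal protein genes lower in 80 of 84 (81; adjusted p = 0.129 with an estimated correlation), with brp at 1.82 ± 0.09 and RpL39 at -1.01 ± 0.08. Muscle markers were lower in 16 of 20 (16 adjusted over the list alone), with adjusted p = 0.104 with an estimated correlation. Hr38 (1.39 ± 0.17), kay (0.55 ± 0.05) and sr (0.99 ± 0.17) were higher with RNAi (edgeR adjusted p = 3.45e-12, 5.71e-17 and 2.48e-07).

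In activated MB477 flies 1364 genes were higher and 1147 lower with RNAi. The eye pigment transporter gene w (X from 2790599 to 2796466) rose from 98.7 ± 6.17 CPM without to 2249 ± 22.9 CPM with RNAi (4.51 ± 0.06), CG18095 was at 0.169 ± 0.166 and 14.6 ± 1.98 CPM, and kek2 fell from 265 ± 2.20 to 28.9 ± 3.09 CPM (-3.19 ± 0.07). Kenyon cell markers were higher in 17 of 23 (18 adjusted over the list alone, median 0.30), with prt at 1.09 ± 0.08 and Dop1R2 at 0.74 ± 0.07, and adjusted p = 0.0993 with an estimated correlation. Antimicrobial and stress peptide genes were higher in 12 of 32 (13 adjusted over the list alone), IM23 by 1.5 ± 0.16, and mitochondrial-encoded genes were lower in 9 of 12 (10), with adjusted p = 0.0993 and 0.131 with an estimated correlation. The mean log2 CPM of the mitochondrial-encoded genes was 6.45, 6.24 and 7.46 in RNAi replicates 1, 2 and 3 and 7.55 ± 0.11 (SD) without RNAi. Without RNAi replicate 3, 12 of 12 were lower (median -0.94, adjusted p = 0.0222 with an estimated correlation), and without RNAi replicate 1 or 2, 7 of 12 (0.181 and 0.179). Muscle markers were lower in 16 of 20 (16 adjusted over the list alone) and photoreceptor markers in 10 of 26 (10), with adjusted p = 0.131 and 0.0729 with an estimated correlation; with all libraries, no list of the 13 that camera called held under it. Hr38 (0.06 ± 0.14) and sr (0.06 ± 0.15) were not past the threshold (edgeR adjusted p = 0.835 and 0.838). The smaller change of kay (-0.14 ± 0.05, adjusted p = 0.0328) did not pass with RLE size factors (-0.12) or without MB477 activated replicate 2 (-0.11) or 3 (-0.14) or RNAi activated replicate 1 (-0.11) or 2 (-0.13), with adjusted p of 0.0110 to 0.169 over the alternatives fixed beforehand.

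Across the 4 RNAi comparisons, which share no libraries, 69 genes were higher and 86 lower in all, against 1.20 and 1.21 for independent lists. Of these, 11 differed by more than 2-fold in every comparison and were singled out after their values were seen: CG18095, CR45284, CG17217, snRNA:U5:34A and w were higher, and kek2, CG31664, CG4839, CG7742, CG17005 and CG13071 lower. In MB131, kek2 stood at 141 ± 9.28 CPM in naive flies and 27.2 ± 1.65 CPM with RNAi (SD, n = 3). Of the other 139 with a position, 54 lie on chromosome arm 2L (38.8%), against 1990 of 11241 tested genes (17.7%).

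**Figure D3:**
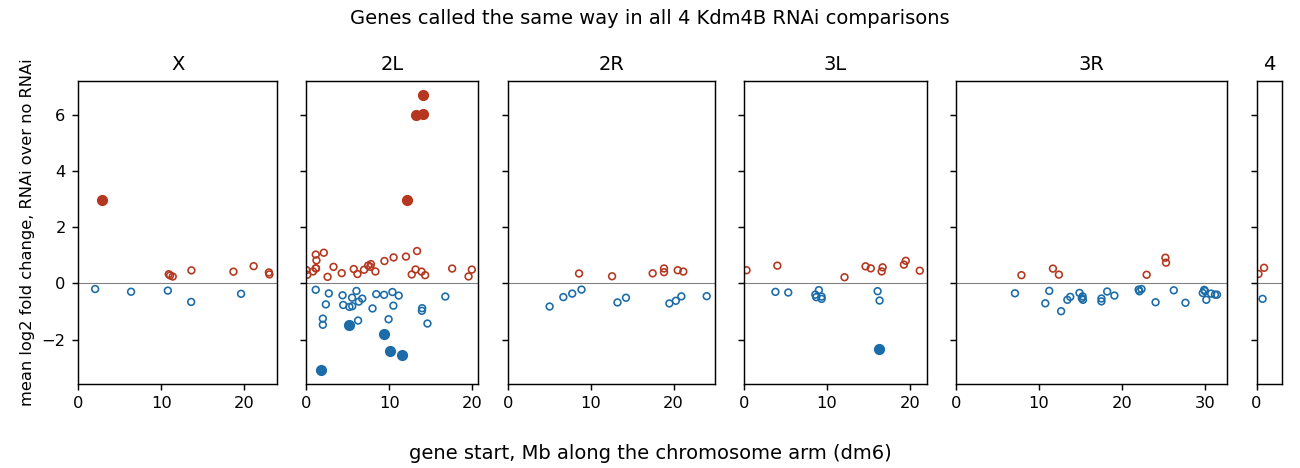
Positions in Mb along the chromosome arms (dm6) of the genes called in the same direction in all 4 RNAi comparisons. The vertical axis gives the mean fitted log2 fold change over these comparisons. It has no bound for snRNA:U5:34A, which is at 0 in some groups, or for CR45284, at 0 in activated MB477 flies without RNAi. Genes that differ by more than 2-fold in each are filled and the others open. Arm 2L holds 54 of the 139 open and 9 of the 11 filled symbols.

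Between the naive groups of the lines, 3320 genes were higher and 3616 lower in MB477 than in MB131. Kenyon cell markers were lower in 20 of 23 (20 adjusted over the list alone, median -1.16): sNPF fell from 528 ± 18.5 to 67.7 ± 1.27 CPM, against 475, 475 and 490.5 CPM in the other naive groups. Presynaptic release genes were lower in 22 of 24 (22 adjusted over the list alone), with brp at -1.76 ± 0.09, and ribosomal protein genes higher in 81 of 84 (81 adjusted over the list alone), RpL39 by 1.18 ± 0.08. Fat body markers were higher in 13 of 18 (13 adjusted over the list alone), Obp99a by 3.22 ± 0.10, and muscle markers in 14 of 20 (14). None of the 15 lists that camera called held with an estimated correlation; for these 5 the adjusted p = 0.135, 0.135, 0.135, 0.135 and 0.215 with an estimated correlation. Genes near the floor in MB131 included CG12661 (0.115 ± 0.0995 against 60.1 ± 4.60 CPM in MB477) and the odorant receptor gene Or65c (0.0557 ± 0.0964 against 10.5 ± 1.39 CPM). Hr38 (-1.35 ± 0.17), kay (-0.43 ± 0.05) and sr (-0.71 ± 0.17) were lower in MB477 (edgeR adjusted p = 1.48e-11, 2.08e-12 and 1.93e-04).

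The authors' deposited table sets activated flies of each line with no RNAi against naive flies, against activated flies with RNAi and against activated flies without CsChrimson. In the authors' deposited table, genes higher in activated MB477 flies numbered 3340, 915 and 2085 in these comparisons, and those lower 3073, 1253 and 2104; for MB131 the higher genes numbered 1197, 585 and 984 and the lower 1107, 622 and 987. By the authors' deposited table, 380 genes were higher in all 3 comparisons of MB477 and 110 in those of MB131, against 47.8 and 5.24 for independent lists, and 36 in both lines. The 3 comparisons of a line share the activated libraries, so part of the excess may come from them. In simulated unchanged groups sharing those libraries, 17 genes were higher in all 3 at an unadjusted p under 0.05 in edgeR. After adjustment 0 were, but with no group changed few genes pass in any comparison, so this 0 does not measure the overlap from sharing. How much of the excess comes from the shared libraries was not determined. In the authors' deposited table kek2 was higher in activated MB131 flies by 0.61 than in naive flies, by 2.64 than with RNAi and by 0.42 than without CsChrimson on the log2 scale. For Hr38 these values were 0.34, -0.80 and 0.30, of which only -0.80 passed the threshold (DESeq2 adjusted p = 0.106, 3.07e-08 and 0.201).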

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

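The tests of the heat shock genes and of the marker lists were chosen only after the results were seen. The tests of a swap and of depth were written before. The test of gene length was added after that of depth, with its bounds set before its result was seen, but a first calculation with misaligned offsets had met the bound for a length bias before the error was found and corrected.

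The differences in response given first were picked out because 2 groups responded differently to the same protocol, as tested by the interaction itself in edgeR or camera. The rise of heat shock genes and the place of the MB477 naive libraries were not picked out by such a test. Responses to activation differed with RNAi for 694 genes in MB131 and 5912 in MB477, with CsChrimson for 714 in MB131 and 5356 in MB477, and between the lines for 5031. Of these counts, 5912, 5356 and 5031 use the MB477 naive libraries, which stand apart. RNAi called 7003 genes in naive and 2511 in activated MB477 flies, so much of the 5912 may lie in the naive levels. The 714 and 5356 use the naive flies without CsChrimson, whose clock genes departed from every other group. With a model of only the compared groups, the real groups gave 712, 5912, 628, 5302 and 5035 genes, and 39 random regroupings of the same libraries gave at most 99, 33, 0, 2786 and 4 in edgeR. Thus 1 of 40 splits was as large in genes past the adjusted threshold. The regroupings put libraries of unlike groups together, which widens the spread within groups and leaves few genes past that threshold. The real groups would tend to give the most for this reason alone, so a random division of the libraries is not excluded by this count. Counts at an unadjusted p under 0.05 in edgeR were 1917, 6374, 1828, 5929 and 5661 for the real groups and at most 2293, 3095, 1130, 4074 and 2719 for the others. At this threshold a regrouping exceeded the real groups for RNAi in MB131. For comparisons of 3 with 3 libraries, the 10 splits are too few for a share under 0.05 (1 of 10 was as large). Real groups gave 2731, 3260, 6834, 3314 and 2150 genes for activation in MB131, MB131 with RNAi, MB477, MB477 with RNAi and without CsChrimson. For RNAi in naive and activated MB131 and naive and activated MB477 they gave 1153, 1521, 6872 and 2605, and between the naive lines 6700. In these 10 comparisons the highest other split gave 0 in edgeR, with at most 713 genes at an unadjusted p under 0.05.

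The Hr38 response differed by 1.33 with RNAi in MB131, by -1.34 with RNAi in MB477, by 1.40 with CsChrimson in MB477 and by 1.41 between the lines on the log2 scale. For kay the last 3 were -0.68, 1.02 and 0.87, and for sr -0.93, 1.0 and 0.53, the last of which lay just inside the threshold. After activation Hr38 stood at 20.4 ± 1.3 CPM in MB477 and 21.2 ± 4.13 CPM in MB477 with RNAi, and before it at 5.96 ± 1.52 and 15.8 ± 0.211 CPM, so that this difference with RNAi lies mostly in the naive levels. For CsChrimson in MB477 the same holds for Hr38 (15.8 ± 1.21 CPM activated and 12.3 ± 0.0994 CPM naive without CsChrimson) and sr (16.2 ± 2.38 and 7.55 ± 0.136 CPM in MB477, 17.5 ± 2.49 and 16.3 ± 2.26 CPM without CsChrimson). For kay, activated flies stood at 316 ± 9.69 CPM in MB477 and 178 ± 9.44 CPM without CsChrimson, so that much of its difference lies in the activated levels. Between the lines, Hr38 differed by -1.35, kay by -0.43 and sr by -0.71 in naive flies, which rest on the MB477 naive libraries. Median differences of the response with RNAi in MB131 were 0.93 for antimicrobial and stress peptides, 0.072 for photoreceptor markers, -0.55 for muscle markers and 0.14 for sex-biased genes, and in MB477 1.20 for cuticle genes. With CsChrimson in MB131 they were -0.31 for Kenyon cell markers, -0.10 for photoreceptor markers, 0.38 for fat body markers and -0.19 for cuticle genes, and in MB477 -0.94 for cuticle genes. Both MB477 medians for cuticle genes use the MB477 naive libraries, which stand apart. For the marker lists, these differences were not separated from unequal shares of RNA from outside the mushroom body.

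Heat shock genes were higher in activated libraries of every genotype. Activation of the neurons through CsChrimson as the whole cause is argued against, since 5 of the 5 genes Hsp83, Hsp26, Hsp23, DnaJ-1 and stv were also called higher without CsChrimson. Reads shared among Hsp70 copies are argued against, because these 5 genes, which are not such copies, rose in 5 of 5 comparisons. A part of the protocol that does not need CsChrimson may account for it: the list median without CsChrimson was 85.9% of that of the other 4 comparisons. Single genes varied: of the 5 comparisons, the one without CsChrimson had the smallest rise of Hsp23 (2.98 ± 0.09) and stv (1.29 ± 0.05). It had the largest of Hsp83 (3.12 ± 0.04), with Hsp26 and DnaJ-1 in between. A further part that differs with CsChrimson or line is not excluded. Light, warmth, handling and the time to collection were not separated by the design.

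The MB477 naive libraries stood apart from the other naive libraries, with lower Kenyon cell and presynaptic transcripts and higher ribosomal protein transcripts. A swap with the other line is argued against: 67 of 69 genes (97.1%) that separate the activated groups of the lines by over 4-fold keep their sign, and so is a lower total count, since 6616 of 6936 calls (95.4%) were made again with every library thinned to the lowest total. Fewer neuronal nuclei with every non-neuronal tissue raised alike is argued against. Median differences were below 0 for markers of hemocytes (-0.21) and glia (-0.12) and above 0 for muscle (0.41) and fat body (0.58). With photoreceptors (-0.23), which are neurons and do not count here, the medians lay 0.811 apart on the log2 scale. Fewer neuronal nuclei with unequal changes in the other tissues was not tested. A length bias between libraries as the whole cause is argued against, because 79.3% of the calls (5389 of 6799) were made again after a trend with gene span was removed from each library, although sNPF went from -2.96 to -2.63 and RpL39 from 1.18 to 0.74, so part of the difference may go with span. The trend with span covered 0.688 to 0.762 on the log2 scale in these 3 libraries and at most 0.461 in any other. A larger share of muscle or fat body RNA, and a true difference of the line that its activated and RNAi groups do not share in full, stay open. On the first principal component those groups lay partway, the activated ones at 18.5 to 22.9 and the RNAi naive one at most at 4.56. The MB131 libraries and those without CsChrimson lay at -25.5 to -12.8. The labels name no batch, so a difference in the preparation of the MB477 naive libraries could not be tested and stays open too.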

How the results depend on the processing

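The 1.5-fold test and the model without the MB477 naive libraries were chosen only after the results were seen. Gene counts of all 15 comparisons stayed within 1.5 times under RLE size factors, no low-count filter, a model of only the compared groups, DESeq2 and limma-voom with sample weights, and without the 3 MB477 naive libraries for the 9 comparisons that do not use them. The replicate block also kept every gene and list count within 1.5 times. Same-numbered libraries did not deviate together (correlations -0.0317 to 0.055), although between the naive lines every library correlated best with its own number. Against a 1.5-fold change, which asks for more by construction, counts were lower. They were 195, 326, 2269, 303 and 138 for activation in MB131, MB131 with RNAi, MB477, MB477 with RNAi and without CsChrimson. For RNAi in naive and activated MB131 and naive and activated MB477 they were 33, 69, 2413 and 120. The RNAi interactions in MB131 and MB477 gave 23 and 2285, the CsChrimson interactions 56 and 1563, the line interaction 1223 and the naive lines 2464. Leaving out a library gave, in the same order, 2319 to 2483, 2624 to 2796, 6278 to 6511, 2791 to 3001 and 1996 to 2184 genes for activation. For RNAi it gave 824 to 1245, 948 to 1118, 6468 to 6699 and 1935 to 2207. The interactions gave 548 to 719, 5606 to 5751, 602 to 796, 5014 to 5223 and 4689 to 4945, and the naive lines 6460 to 6678. The 824 is without MB131 naive replicate 1, and the cause was not tested.

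With an estimated correlation, lists called by camera went from 17, 15, 17 and 18 to 7, 4, 3 and 4 for activation in MB131, MB477, MB477 with RNAi and without CsChrimson. They went from 11, 14, 13 and 13 to 4, 5, 1 and 0 for RNAi, from 13, 14, 11, 9 and 9 to 4, 1, 4, 1 and 0 for the interactions and from 15 to 0 between the naive lines. The fry test, which does not compare a list with other genes, called 23 and 33 lists for activation in MB131 with RNAi and MB477. It called 32 and 23 for RNAi in naive and activated MB477, 34 and 29 for the RNAi and CsChrimson interactions in MB477, 29 for the line interaction and 35 between the naive lines. Without the low-count filter camera called 14 lists for the CsChrimson interaction in MB477 and 15 for the line. The cause was not tested.

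Some changes that did not pass turned in sign without single libraries. For Hr38 the CsChrimson interaction in MB131 ran from -0.072 to 0.063 (turned without MB131 naive replicate 1, MB131 activated replicate 3 or activated replicate 1 without CsChrimson), and RNAi in activated MB477 from -0.12 to 0.15 (RNAi activated replicate 2). For sr the RNAi interaction in MB131 ran from -0.27 to 0.086 (MB131 activated replicate 1 or RNAi naive replicate 3). RNAi changed sr by -0.025 to 0.29 in activated MB131 (activated replicate 2) and -0.056 to 0.14 in activated MB477 (activated replicate 2). Low counts limit Kdm4B, at 2 to 26 reads per library. Over the alternatives its change ran from -0.59 to -0.063 in activated MB131, -0.11 to 0.49 in naive MB131 (turned without RNAi naive replicate 2), -1.48 to -0.47 in activated MB477 and -0.55 to 0.31 in naive MB477 (turned without MB477 naive replicate 1 or 2 or RNAi naive replicate 3), and none passed the threshold.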

Other observations

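The tests of a single genome window and of the protocol as the cause of the clock gene change were chosen only after the results were seen. The pairing of tim with Pdp1 and of vri with per was set then too, so the protocol test restates known values. Those of chromosome arm 2L and of the time of day were written before.

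Transcripts of organs outside the brain appeared in a few groups. In naive flies without CsChrimson, Peb, which encodes an ejaculatory bulb protein, stood at 13.5 ± 6.65 CPM and was at 0 in all 3 activated libraries, at least 153-fold lower with a floor of 3 counts over the group. PebII and the seminal fluid gene Sfp87B were at least 38.9-fold and 28.5-fold lower. edgeR called Peb (adjusted p = 1.33e-14) but DESeq2 did not (adjusted p = 0.328, and 3.99e-25 to 0.328 over the alternatives fixed beforehand). DESeq2 also did not call PebII (adjusted p = 0.467, and 2.15e-08 to 0.467) or Sfp87B (0.500, and 2.62e-07 to 0.500). In naive MB477 flies with RNAi, the digestive protease genes Jon65Aiv, betaTry and alphaTry stood at 2.73 ± 1.42, 2.52 ± 0.785 and 2.42 ± 1.26 CPM and were at 0 in the activated group, at least 24.8-fold, 23.0-fold and 22-fold lower. No gene list for these organs was fixed, so they were not tested as groups.

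Histone lysine demethylases and methyltransferases, the class of Kdm4B, had 3 of 24 higher and 1 lower genes after activation in MB131 (3 and 1 adjusted over the list alone, median -0.03, camera adjusted p = 0.763). Of them, 2 of 24 were higher with RNAi in naive MB131 flies (2 adjusted over the list alone, camera adjusted p = 0.496). After activation in MB477 13 of 24 of this class were higher and 5 lower (13 and 5 adjusted over the list alone, median 0.32, camera adjusted p = 0.137). The heterochromatin and piRNA list had a median of -0.08 with RNAi in naive MB131 flies (camera adjusted p = 0.520). Long-term memory genes had 6 of 27 higher and 5 lower after activation in MB131 (7 and 6 adjusted over the list alone, camera adjusted p = 0.763). In MB477 they had 16 of 27 higher and 8 lower (16 and 8 adjusted over the list alone, median 0.55, camera adjusted p = 0.0826). Both MB477 values rest on the naive libraries that stand apart. In MB477 with RNAi, 12 of 27 long-term memory genes were lower and 3 higher (12 and 3 adjusted over the list alone, camera adjusted p = 0.0144, and 0.347 with an estimated correlation).

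Genes that differed by more than 2-fold in all 4 RNAi comparisons lay mostly on chromosome arm 2L, 9 of 11. For a genotype difference at a single place, the fullest window of 1 Mb held 27.3% of them, which met neither bound set for this test. That window held 3 genes, against a median of 2 and at most 4 in 1000 random sets. The 9 genes on 2L start between 1824172 and 14032006, and CG13071 lies on 3L and w on X. These positions argue against a single place that holds all 11. A genotype difference along arm 2L is a candidate explanation: of the other 139 genes called the same way in all 4 comparisons, 38.8% lie on 2L, against 17.7% of tested genes, 2.19 times that share (two-sided Fisher's exact test, p = 3.39e-09, although neighbouring genes are not independent). Genes called over 2-fold lay on 2L in 46.6% of cases for RNAi in naive MB131, 35.6% in activated MB131, 28.5% in activated MB477 and 19.1% in naive MB477, and in 12.8% to 19.0% for the activation comparisons. Such differences would come with the chromosome that carries an RNAi construct or its controls and not from a lower Kdm4B level. The labels do not give the construct or its place, and an effect of Kdm4B on these genes stays open. The w gene, a common marker on fly transgenes, was also higher in all 4 comparisons.

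Clock genes were lower in activated than in naive flies without CsChrimson, with tim at 2121 ± 169 CPM in the naive group and 831 ± 15.9 CPM after activation. It is the naive group that departed. In every other group tim stood at 711 to 1081 CPM. For vri the other groups lay at 60.8 to 226 CPM against 379 ± 32.6, and for Pdp1 at 1490 to 1962 CPM against 2899 ± 153. The activated group without CsChrimson lay among the others. A hypothesis is collection at different times of day, which the labels do not give: in the same flies cwo was also lower (-0.23 ± 0.05, edgeR adjusted p = 8.65e-05) and cry higher (0.56 ± 0.05, edgeR adjusted p = 1.72e-16), as was Clk (0.71 ± 0.05), a change this explanation allows. In MB131 tim (-0.60), cwo (-0.39) and cry (0.18) moved in the same directions, but Pdp1 (-0.10) and Clk (0.0005) did not pass the threshold, and in MB477 cry (0.43) and Clk (0.56) were higher where tim was not lower, so neither sets a time alone. The protocol as the whole cause, with the same direction in each genotype, is argued against for tim and Pdp1, which were higher after activation in MB131 with RNAi (0.17 ± 0.04 and 0.30 ± 0.04). For vri and per it cannot be told apart from the time of day, since vri fell in MB131 (-0.70), MB131 with RNAi (-0.34), MB477 with RNAi (-0.32) and without CsChrimson (-1.76), and per in 3 of these 4, with MB131 with RNAi at 0.05 and not past the threshold, while in MB477, whose naive libraries stand apart, vri rose (1.05).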
